A study of Homo sapiens with 2 samples.

How the data were processed

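RNA was measured in HEK293 cells, a human embryonic kidney line, transfected with FLAG-tagged TOP3B carrying the R338W substitution. There were 2 libraries. The input library was made from lysate without an antibody step, and the RIP (RNA immunoprecipitation) library was made from RNA recovered with a monoclonal anti-FLAG antibody. Per the labels' protocols, immunoprecipitation and RNA extraction followed a commercial RIP kit, and libraries were prepared with a stranded total RNA kit. The labels give 15 as the passage number of both samples. Each group held 1 library, so groups were assigned directly from the sample titles.

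The submitters' processing notes name cutadapt 1.18, Trimmomatic 0.3, STAR 2.6.1, RSEM 1.2.31 and the genome build hg38. The settings, the order of steps, the gene annotation release and the filter on low genes are not given in the sources used here. The authors deposited 1 table of 13075 genes with 1 value per library. The unit is not named in the table, and was taken as FPKM (fragments per kilobase of transcript, scaled to the library's total) because the deposited values carry decimals, sum to 1090240 in the RIP and 1512050 in the input, and fall on steps that shorten with transcript length. FPKM divides by transcript length and by the total of the same library, so a few very abundant RNAs lower the values of all other genes in that library. Gene names holding a separator sign were spread over several columns in 36 rows and were rejoined. In 19 rows the symbol had turned into a calendar date, and the Ensembl identifier was used to restore it.

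Depth was estimated from the values. Where a gene has 1 transcript and fragments are counted whole, its FPKM should be a multiple of the value of 1 fragment, and the depth and mean fragment length that best gave whole fragments were searched for. This gave about 25000000 fragments with a mean length of 171 bases for the RIP, and 15300000 with a mean length of 167 bases for the input. With those settings 55.9% of 340 genes in the RIP and 62.2% of 418 genes in the input lay within 0.15 of a whole fragment. The same search on 1 shuffle of transcript lengths between genes gave 36.4% of 478 genes in the RIP and 34.5% of 730 in the input, and its mean cosine score, the quantity maximised, was 0.099 and 0.112 against 0.267 and 0.416 for the real lengths. Many genes did not fall on whole fragments, so the depths are estimates. A value of 5 FPKM on a transcript of 2000 bases stood for about 229 fragments in the RIP and 140 in the input. Fragment numbers of genes with several transcripts used the median annotated length and are approximate.

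The ratio of each gene was log2((RIP + 1)/(input + 1)), with a pseudocount of 1 FPKM, so it understates differences of low genes. Genes with at least 5 FPKM in at least 1 library entered the comparison, which left 11990 genes and removed 1085. Genes at least 2-fold apart on this scale were counted in each direction. No p-value or SD was computed, because neither group had a replicate and genes are not replicates. For 30 gene lists, the median ratio was given with its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. Where transcript length or retained-intron transcripts were matched as well, 10 expression bins were used and each was split into 5. Such percentiles thus differ from the main ones in the expression bins too. The percentile describes these libraries and is not a p-value. Percentiles below 2.5 or above 97.5 were used as limits for describing a list as standing apart, and these limits were set after the data had been examined. Percentiles were given for the 27 lists with at least 3 measured members.

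Transcript length, GC content, gene class and coordinates came from GENCODE release 29 on GRCh38, the same assembly as hg38, matched by Ensembl identifier for 12983 of 13075 genes (99.3%). GC content was that of the transcript nearest to the gene's median annotated length. Intervals of a median are 95% confidence intervals of the median over genes and narrow as the number of genes grows. They describe neither the spread of single genes nor that of experiments. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures used matplotlib 3.10.9.

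The gene lists, the measure, the floor, the first set of other settings and the rule for naming genes were fixed before the data were examined. The rule took the members of the TOP3B list past the floor, the 12 highest and 12 lowest ratios, up to 2 highest and 2 lowest members per list, and the 5 highest values per library. Some genes that the rule takes are not reported here. Genes named outside it are said to have been chosen afterwards. The alternatives were other pseudocounts, floors and fold limits, 2 other scalings, and other matchings of the random lists. Count-based scaling with TMM or DESeq2 size factors was planned only for counts and was not run, since the table holds FPKM.

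The ratio was tested on simulated libraries of 11304 genes drawn with Poisson error from the estimated fragments. For RIP against input, the 2-fold limit was passed in the right direction by 0% of 48 genes simulated at 1.5-fold, 91.8% of 49 at 2.5-fold, 100% of 50 at 3-fold and 100% of 47 at 4-fold. Of 11110 unchanged genes 92 passed the limit, and 0 of the 10860 with at least 50 fragments did. This covers counting error alone and gives no rate of false calls between libraries. A simulated list of 40 genes shifted by 0.3 log2 reached percentile 100, and an unshifted list of 40 genes reached 9.66. Unchanged genes varied there by counting error alone, so this does not give the power for lists in the real libraries. In the real libraries the middle 95% of random lists matched to 38 mitosis genes ran from -0.04 to 0.41. The depth search returned the simulated depth to a ratio of 1, but the simulation followed the search's own model of whole fragments. It is no check of the depths estimated for the real libraries.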

Results

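The series asked which RNAs are held in complexes with TOP3B, a topoisomerase that acts on DNA and RNA and works with the proteins TDRD3 and FMRP. The tagged R338W form was immunoprecipitated from HEK293 cells, and its RNA was compared with the input of the transfected cells. The table held 13075 genes for 1 RIP and 1 input library, with estimated depths of 25000000 and 15300000 fragments. Neither library had a replicate, so each difference below is a difference between 2 libraries with no replicate check. A RIP from cells without the tagged protein was not analysed here.

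The transcript of the bait was reported first. TOP3B (ENSG00000100038.19, GRCh38 chromosome 22, 21957025 to 21982816, minus strand) stood at 30666 FPKM in the RIP and 15062 FPKM in the input, a log2 ratio of 1.03. This was 1469 times the median coding gene in the RIP and 799 times in the input. It made up 2.81% of summed FPKM in the RIP and 0.996% in the input. The values do not separate the transfected copy from the chromosomal gene. Relative to the median gene of each library the log2 ratio was 0.91, which lies under the 2-fold limit, and after rescaling without abundant RNA classes, a setting added after seeing the data, it was 1.16.

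The transcripts of TOP3B's partners lay near the median gene. TDRD3, its scaffold partner, stood at 15.5 FPKM in the RIP and 14.4 in the input, and FMR1, which encodes FMRP, at 104 and 82.3 FPKM. The paralogs FXR1 (93.1 and 85.0 FPKM) and FXR2 (38.2 and 34.2 FPKM) had log2 ratios of 0.13 and 0.16. The ubiquitin ligase TRIM41 had a log2 ratio of -0.05, and the repair enzymes TDP1 and TDP2 had 0.27 and -0.15. The related TOP3A had 0.22, and its partners RMI1 and RMI2 had -0.65 and -0.33. BLM, the helicase of the same complex, stood at 53.6 FPKM in the RIP and 30.6 in the input, a log2 ratio of 0.79. Over the 12 members the median was 0.14, at percentile 51.2 of random lists, and TOP3B alone was at least 2-fold higher.

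A few noncoding RNAs had the highest FPKM values in both libraries and were lower in the RIP. RN7SK, which holds back a transcription elongation factor, stood at 109332 FPKM in the RIP and 162570 in the input. RN7SL1, the RNA of the signal recognition particle, stood at 101210 and 181363 FPKM, and a further copy listed as Metazoa_SRP (ENSG00000274012.1) at 85998 and 199593 FPKM. RNY3, a Y RNA, stood at 33569 and 90297 FPKM. The 5 highest genes of each library took 33.1% of summed FPKM in the RIP and 44.4% in the input. TOP3B is among those of the RIP. Protein-coding genes took 48.5% and 30.9% of summed FPKM. FPKM divides by length, so these are not shares of fragments. RNY3 rested on about 1028 estimated fragments in the RIP and 1693 in the input.

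Most genes, 11102 of 11990, lay within 2-fold of the input. Of 11990 genes, 588 (4.90%) were at least 2-fold higher in the RIP and 300 (2.5%) at least 2-fold lower. The median log2 ratio was 0.13, with quartiles of -0.25 and 0.50. Among protein-coding genes alone 384 of 10513 were higher and 56 lower, and among genes with at least 50 estimated fragments 507 were higher and 138 lower, both settings chosen after seeing the data. At a 4-fold limit 79 were higher and 84 lower. Of the genes past the limit, 44.8% were higher after centring on the median gene and 83.0% after rescaling without abundant RNA classes, so the balance of directions depended on the scaling. Either scaling moved ratios by 0.13 log2, centring downwards and rescaling upwards, and the list medians below are to be read against the median gene at 0.13.

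The genes at the ends of the ranking by the fixed rule were mostly short RNAs with few fragments, and 4 of the 24 had no annotation match and so no known length. All 12 with the highest ratios were listed at 0 in the input, and 8 of them rested on under 3.5 estimated fragments. They included the U6 pseudogenes RNU6-314P (31.7 FPKM in the RIP) and RNU6-988P (25.1 FPKM), and SNORA51 (24.8 FPKM). Of the 12 with the lowest ratios, 9 were listed at 0 in the RIP, among them SNORA18 (70.4 FPKM in the input) and SNORA64 (58.9 FPKM). The 2 with at least 50 fragments were copies of the ribosomal RNA gene RNA5-8S5, each at 189 FPKM in the RIP and 6313 in the input. The copies share their sequence, so their equal values are 1 measurement. SNORA67 stood at 1.77 FPKM in the RIP and 302 in the input.

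**Figure D1:**
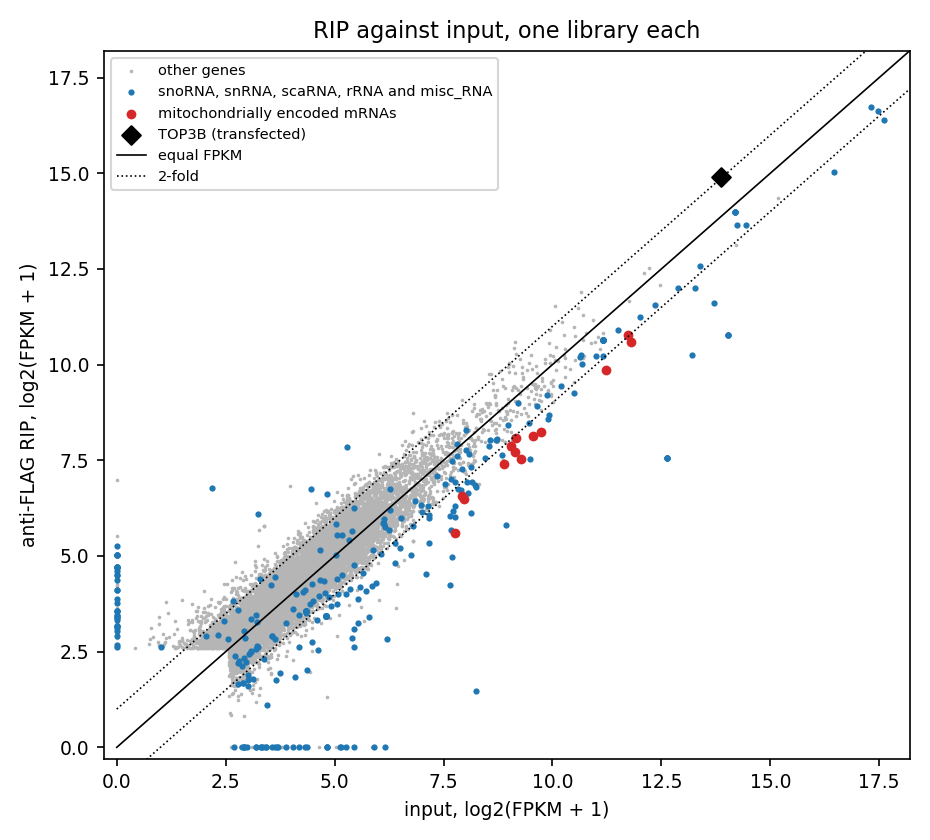
Each point is 1 of 11990 genes, with the input on the x axis and the anti-FLAG RIP on the y axis, both as log2(FPKM + 1); the solid line marks equal values and the dotted lines a 2-fold difference. TOP3B lies at 30666 FPKM in the RIP, mitochondrially encoded mRNAs lie below the solid line, and the points on either axis are genes listed at 0 in 1 library.

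Mitochondrially encoded mRNAs, which encode core subunits of the respiratory chain, were the lowest of the lists. Of 13 members, 12 were at least 2-fold lower in the RIP, with a median log2 ratio of -1.42 at percentile 0 of random lists. MT-ND6 stood at 47.2 FPKM in the RIP and 217 in the input, and MT-ATP8 at 183 and 622 FPKM. MT-CO1, the member nearest to the input, stood at 1739 and 3424 FPKM. The medians of nuclear genes for mitochondrial proteins were lower by less, and few members passed the 2-fold limit. In the nuclear-encoded respiratory chain 3 members were at least 2-fold lower and 0 higher, with 53 ratios below 0 and 18 above. Among mitochondrial ribosomal proteins 0 were lower and 1 higher, with 57 ratios below 0 and 19 above. The nuclear-encoded respiratory chain had a median of -0.29 over 71 genes (percentile 0), with COX6C at 67.6 and 144 FPKM and NDUFA13 at 286 and 169. Mitochondrial ribosomal proteins had a median of -0.25 over 76 genes (percentile 0), with MRPL47 at 16.8 and 32.5 FPKM and MRPS15 at 163 and 70.5.

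Small structured RNAs were also lower, and the median of cytosolic ribosomal proteins was lower by less. All 30 measured small structured RNAs had ratios below 0, 11 of them by at least 2-fold, with a median of -0.83 (percentile 0). The minor spliceosomal RNA RNU6ATAC stood at 381 FPKM in the RIP and 953 in the input, and RNU12 at 509 and 592. Cytosolic ribosomal proteins had a median of -0.23 over 79 genes (percentile 0.385), and members went both ways. Ratios were below 0 in 51 and above 0 in 28, and 3 members were at least 2-fold higher and 1 lower. RPS13 stood at 260 and 538 FPKM and RPS15A at 746 and 1435, whereas RPL19 stood at 3822 and 1618. The percentile was 17.1 with a floor of 20 FPKM. Translation initiation and elongation factors had a median of 0.20 (percentile 75.2), with EIF4A2 at 410 and 208 FPKM and EIF3E at 87.6 and 152.

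Host genes of snoRNAs had a median of -0.38 over 18 genes (percentile 0.13), with SNHG3 at 16.3 FPKM in the RIP and 44.8 in the input and SNHG1 at 327 and 169. Nuclear long noncoding RNAs had a median of -0.37 over 10 genes (percentile 0.78). NORAD, listed as LINC00657, stood at 30.6 and 51.5 FPKM, but is known as a mainly cytoplasmic RNA and so goes against the name of the list. FTX stood at 47.2 and 33.9 FPKM. Matched also on annotated retained-intron transcripts, the nuclear long noncoding list lay at percentile 9.71. C2H2 zinc-finger transcription factors had a median of -0.14 over 115 genes (percentile 0), and of -0.02 after rescaling without abundant RNA classes. ZNF281 stood at 10.1 and 19.0 FPKM, and ZNF282 at 32.7 and 15.5.

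Messenger RNAs known from brain as classical FMRP targets were the highest of the lists with at least 3 measured members. Of 56 members, 55 had ratios above 0 and 10 were at least 2-fold higher, with a median of 0.70 at percentile 100. CHD6, a chromatin remodeller, stood at 150 FPKM in the RIP and 54.9 in the input, and HERC2, a ubiquitin ligase, at 53.5 and 19.9. PCLO, a presynaptic scaffold, was the exception at 4.15 and 5.34 FPKM. Matching on transcript length as well left the list at percentile 100, but the length bins were coarse. The list's median longest transcript was 10685 bases, whereas the top length quintile of coding genes began at 6096. Length within a bin was not held equal, so the match cannot exclude length. Without 2 members shared with other lists the median was 0.74. Chromatin genes such as CHD6 were placed in this list alone, so this does not separate it from the chromatin list below. Synapse and axon genes had a median of 0.42 over 21 genes (percentile 98.5), with the sodium channel SCN8A at 14.3 and 4.54 FPKM and VAMP2, a synaptic vesicle protein, at a log2 ratio of -0.38. That list lay at percentile 90.2 when transcript length was matched.

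Genes for very large proteins and for chromatin were higher as well. Very large cytoskeletal and scaffold proteins had a median of 0.64 over 36 genes (percentile 100), 8 of them at least 2-fold higher. RNF213, a giant ubiquitin ligase, stood at 308 FPKM in the RIP and 111 in the input, and the actin crosslinker FLNA at 369 and 167, while AHNAK stood at 16.9 and 16.4. Chromatin modifiers and remodellers had a median of 0.60 over 52 genes (percentile 100), 9 of them at least 2-fold higher. DNMT1, the maintenance DNA methyltransferase, stood at 334.2 and 135.5 FPKM and CHD7 at 36.0 and 14.5, while TET1 stood at 6.98 and 10.0. Extracellular matrix genes had a median of 0.47 over 34 genes (percentile 99.9, or 96.3 with length matched), with LAMA3 at 41.7 and 18.5 FPKM and ITGB1 at 71.0 and 97.7.

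Topoisomerase and DNA repair genes had a median of 0.45 over 48 genes (percentile 99.9), with RAD54L at 54.2 FPKM in the RIP and 21.8 in the input and MSH6 at 58.8 and 92.4. Splicing factors and hnRNPs had a median of 0.36 over 69 genes (percentile 99.3, or 89.8 with length matched). SF3A1 stood at 94.6 and 38.3 FPKM and PRPF6 at 69.0 and 28.9, while SNRPF stood at 23.7 and 47.6. P-body, stress-granule and RNA decay factors had a median of 0.40 over 45 genes (percentile 97.6, or 63.3 with length matched), with the deadenylase subunit PAN2 at 128 and 46.7 FPKM and CNOT7 at 26.8 and 37.5.

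The other lists lay within the limits when matched on expression. Mitosis genes had a median of 0.38 (percentile 95.3, or 99.0 with retained-intron transcripts matched and 98.8 unmatched), with SMC4 at 361 FPKM in the RIP and 157 in the input and MAD2L1 at 29.2 and 53.6. Immediate-early genes had a median of 0.39 (percentile 95.5, or 97.9 with length matched and 99.8 with retained-intron transcripts matched), with CYR61 at 96.7 and 43.0 FPKM and BTG2 at 22.9 and 37.0. DNA replication genes had a median of 0.27 (percentile 80.1), with MCM10 at 71.1 and 27.6 FPKM and RPA2 at 35.5 and 47.7. Glycolysis genes had a median of 0.23 (percentile 71.8), with HK1 at 39.0 and 23.4 FPKM and GAPDH at 942 and 1350. Heat shock genes had a median of 0.15 (percentile 65.4), with HSP90AA1 at 904 and 445 FPKM and HSPE1 at 81.7 and 153. The medians of 4 further lists changed sign when centred on the median gene. They were the proteasome (0.11, percentile 33.4), histones (0.08, percentile 39.7, or 99.9 with length matched), interferon-stimulated genes (0.07, percentile 42.4) and cholesterol synthesis (0.06, percentile 23.5).

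Few markers of kidney tubule, liver or blood cells were in the deposited table. Its filter on low genes is not given, so a missing marker cannot be read as not expressed. Of 17 kidney tubule markers only LRP2 was measured, at 5.49 FPKM in the RIP and 1.96 in the input. The 14 liver and 13 blood cell markers gave no values here.

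**Figure D2:**
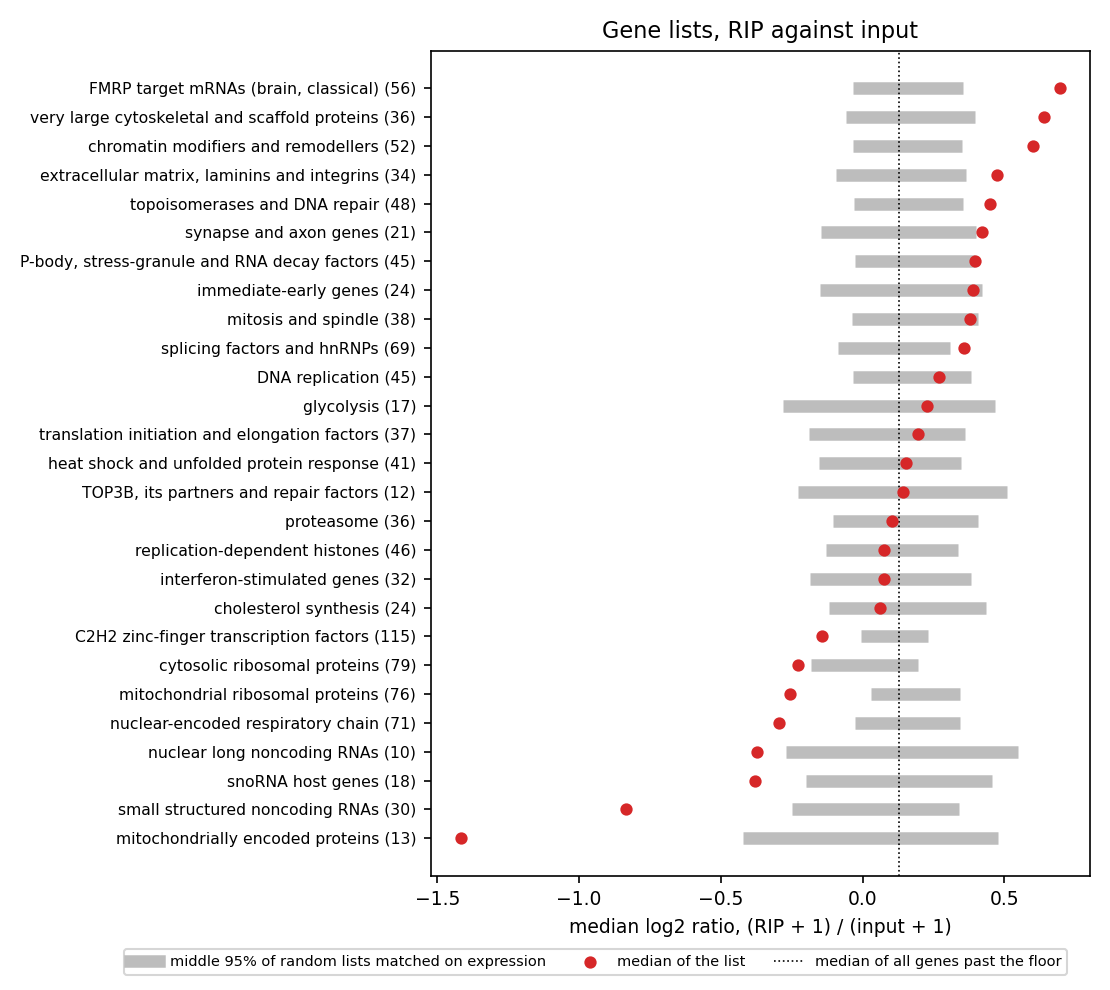
Red points give the median log2((RIP + 1)/(input + 1)) of each of 27 gene lists, with the number of measured genes in brackets; grey bars hold the middle 95% of 10000 random lists matched on expression, and the dotted line marks the median of all genes (0.13). Mitochondrially encoded mRNAs lie at -1.42 and FMRP targets at 0.70, both outside their bars.

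By gene class, the medians of short noncoding RNAs were lower in the RIP and that of protein-coding genes slightly higher. The 125 snoRNAs had a median log2 ratio of -1.07, the 17 scaRNAs -1.02 and the 80 snRNAs -0.53. Members went both ways, with 14 snoRNAs at least 2-fold higher and 63 lower, 2 scaRNAs higher and 9 lower, and 12 snRNAs higher and 16 lower. The snRNAs held 51 distinct pairs of values. The 21 rows of ribosomal RNA had a median of -1.36, but held 3 distinct values. Protein-coding genes had a median of 0.15, and 215 unprocessed pseudogenes had 0.54, although fragments of such copies can be assigned to their parent genes or the reverse. The 38 genes annotated inside introns on the sense strand had a median of -0.67. Processed pseudogenes, long noncoding and antisense genes had medians of -0.15, -0.05 and -0.06, and each turned positive after rescaling without abundant RNA classes. At the 2-fold limit 29 processed pseudogenes were higher and 38 lower, against 28 and 10 long noncoding and 37 and 12 antisense genes.

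Coding genes with a longer longest transcript had higher ratios. The median ran over quintiles of that length from -0.09 to 0.33, and over quintiles of GC content from 0.02 to 0.27. By median annotated transcript length the quintiles ran from 0.18 to 0.13 instead. Among the 442 coding genes with 1 annotated transcript the difference between top and bottom quintile was -0.31, and 32 of the 89 genes of that bottom quintile were histones. Without the listed histones the difference was -0.08, with an interval over genes of -0.28 to 0.06. Mitochondrially encoded mRNAs, with a median length of 784 bases, were kept in both sets.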

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

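No paired analysis was possible because each group has 1 library. TMM and DESeq2 scaling were not run, since the table holds FPKM. Settings marked as added were chosen after seeing the data, and causes were not tested unless stated. Of the list medians and percentiles, 375 values kept their side or stayed within the interval over genes. Of the others, 10 medians moved, 15 percentiles came inside the limits and 5 went beyond them. Of the named-gene values 402 were counted as unchanged and 117 as moved. Of the named genes at least 2-fold apart 0 changed sign, but this was fixed in advance. Another pseudocount or floor keeps the sign, and either scaling shifted ratios by 0.13 log2. Depth limits short RNAs most, where 1 fragment can pass the floor.

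Against 588 higher and 300 lower genes and a median of 0.13, pseudocount 5 gave 300, 180 and 0.10, and a floor of 20 FPKM 352, 157 and 0.21. Centring on the median gene gave 365 higher and 450 lower genes, so that lower genes outnumbered higher ones. Rescaling without abundant RNA classes gave 951, 195 and 0.26, and shifted ratios by 0.13. The 1.5-fold limit gave 2386 and 1222 genes, and the 4-fold limit 79 and 84. Coding genes alone (added) gave 384, 56 and 0.15, and at least 50 fragments (added) gave 138 lower genes. TOP3B had 0.91 relative to the median gene and 1.16 after rescaling (added).

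Centring moved the medians of mitochondrial ribosomal proteins to -0.38, mitochondrially encoded proteins to -1.55, the respiratory chain to -0.42, FMRP targets to 0.57, zinc-finger factors to -0.27, splicing factors to 0.23 and P-body factors to 0.27. Rescaling (added) moved zinc-finger factors to -0.020, the proteasome to 0.24 and cholesterol synthesis to 0.19.

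With a floor of 20 FPKM the percentile of cytosolic ribosomal proteins was 17.1, of synapse genes 87.7, of extracellular matrix 95.5 and of P-body factors 97.0. Synapse genes lay at 96.8 without a floor. P-body factors lay at 96.7 with pseudocount 5 and 97.4 with 50 fragments (added). With transcript length matched, histones lay at 99.9, synapse genes at 90.2, splicing factors at 89.8, immediate-early genes at 97.9, extracellular matrix at 96.3 and P-body factors at 63.3. With retained-intron transcripts matched (added), nuclear long noncoding RNAs lay at 9.71, synapse genes at 96.9, mitosis at 99.0, splicing factors at 96.4, immediate-early genes at 99.8 and P-body factors at 90.8. Mitosis lay at 98.8 with unmatched lists.

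The length difference of 0.42 was 0.33 with pseudocount 5 and 0.56 with a floor of 20 FPKM. It turned to -0.31 in genes with a single transcript and -0.050 by median transcript length (both added). The GC difference of 0.26 was 0.20 with pseudocount 5, 0.21 with a floor of 20 FPKM and 0.65 in genes with a single transcript (added). With pseudocount 5 the class medians were -0.51 for snRNA, -1.10 for ribosomal RNA, 0.41 for unprocessed pseudogenes and 0.12 for coding genes. With a floor of 20 FPKM they were -1.93 for the 2 genes left inside introns, 0.67 for unprocessed pseudogenes and 0.23 for coding genes.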

Other observations

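The coding genes named first, the readthrough and retained-intron groups, and the tests of GC content against length, of length and GC content against retained introns and of genes inside introns, were chosen only after the data had been seen. Among coding genes with at least 50 estimated fragments, several for core transcription and splicing stood high. EFTUD2, a GTPase of the U5 spliceosomal particle, stood at 424 FPKM in the RIP and 110 in the input, and POLR2A, the largest subunit of RNA polymerase II, at 201 and 64.2. GABRE, a GABA receptor subunit, stood at 129 and 40.4 FPKM. At the other end CD68, a lysosomal glycoprotein, stood at 9.34 and 28.6 FPKM, MZT1, a spindle pole protein, at 6.78 and 16.7, and UBE2K, a ubiquitin-conjugating enzyme, at 11.9 and 26.9.

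Readthrough genes, whose annotated transcripts join exons of neighbouring genes, also stood high. Their 56 members had a median log2 ratio of 0.54 against 0.15 for other coding genes, with 14 at least 2-fold higher and 0 lower. ZFP91-CNTF had a log2 ratio of 2.68, and TSNAX-DISC1 stood at 6.77 FPKM in the RIP and 1.47 in the input. These transcripts share most exons with their parent genes, so their values depend on how fragments were divided among them.

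Coding genes with annotated retained-intron transcripts had higher ratios, with a median of -0.05 in 4047 genes with none and 0.43 in 2224 genes with 4 or more. With 1, 2 or 3 other transcripts the difference between genes with and without one was 0.34, 0.32 and 0.38. This argues against the number of other transcripts as the whole cause. The total number of isoforms was not held equal, because each retained-intron transcript adds to it, so that number stays open. The smallest difference over 6 groups was 0.21, in the group of 9 to 175 other transcripts, where the number still varied. Within quintiles of longest transcript length the smallest difference was 0.13, but length still varied within a quintile, so that length is not excluded. Within GC quintiles the difference ran from 0.23 to 0.41. Genes annotated inside introns lay below coding genes by a difference of -0.82, but 2 of the 38 reached 20 FPKM, so genomic DNA or intron RNA at large stays open. Spliced and unspliced RNA were not compared here, and no biological explanation was tested.

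The higher ratios of coding genes with a longer longest transcript held within GC quintiles. Over 5 GC quintiles the smallest difference between top and bottom length quintile was 0.42, which argues against that GC content alone. It was taken from the transcript nearest to the gene's median length, so the GC content of the longest transcript stays open. Genes over 6 kb and genes of 3 to 4 kb differed by 0.18, but 62.6% of those over 6 kb had a median annotated transcript under 2000 bases, so an error in the effective length of short transcripts stays open. In genes with 1 annotated transcript the difference was -0.31, or -0.08 with an interval of -0.28 to 0.06 without the listed histones. Both sets kept the mitochondrially encoded mRNAs, with a median length of 784 bases and a median log2 ratio of -1.42. The difference without them was not computed. Whether the trend reflects which isoforms the fragments were assigned to therefore stays open. Among genes with no annotated retained-intron transcript a difference of 0.25 remained, so annotated retained-intron transcripts do not account for all of the length trend. Retained introns outside the annotation were not measured and stay open.

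Mitochondrially encoded mRNAs were lower in the RIP than nuclear mRNAs of similar length or abundance. Their median lay at percentile 0 of 10000 nuclear lists matched on length, whose lowest median was -0.74. It also lay at percentile 0 of lists drawn from the 200 most abundant nuclear coding genes, whose lowest was -0.57. Short length and high abundance are thus argued against. No biological explanation was tested.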
